A study of Homo sapiens with 8 samples.

How the data were processed

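Gene expression was measured by RNA sequencing in WSU-DLCL2, an established human diffuse large B-cell lymphoma line. Per the labels, control cells and cells overexpressing FDX1 (FDX1-OE) received 15 nM elesclomol (ES), a small molecule that carries copper into cells, or the solvent DMSO, for 48 h. The 4 groups (control DMSO, FDX1-OE DMSO, control ES and FDX1-OE ES) held 2 libraries each, 8 in all. Total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit. Whether the 2 libraries of a group came from separate cultures is not stated, so every p-value measures only the spread between these samples, which may be technical.

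The deposited values are taken as FPKM, made by the authors as fragments scaled to the length of the gene model and the size of the library, with 1 value for each of 60592 gene symbol rows in each library. No header names the unit: it was read from the values, which are not whole, whose sums differ between libraries, and whose commonest low value recurs at its multiples. The submitters' processing notes name HISAT2, HTSeq, R 3.2.0 and the hg19 build without giving their roles, and the tool that made the deposited FPKM is not stated. The absolute depth and the handling of strands are not given. The commonest low value, taken as 1 fragment in the shortest gene models, lay between 0.138 and 0.164 FPKM. It placed the relative depths of the libraries within 1.18 of each other. In the deposited files 1059 rows share a symbol with another row, 38 of them among the genes tested. They were kept apart and none is named.

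The plan written before the data were examined assumed counts and gave a second course for a normalised unit, which was followed because the files hold FPKM and no counts. The comparisons, gene lists, rule for named genes and most alternative settings were fixed before the data were examined. Values were used as log2(FPKM + 1), so fold changes are on that scale, which understates the change of genes with low values. Genes with at least 1 FPKM in at least 2 libraries were tested, 12063 in all, with no scaling beyond that of the authors. limma 3.58.1 under R 4.3.3 fitted 4 group means to all 8 libraries with a mean-variance trend (4 residual degrees of freedom and 4.25 prior degrees of freedom). All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The 5 comparisons were FDX1-OE against control in DMSO, FDX1-OE against control in ES, ES against DMSO in control cells, ES against DMSO in FDX1-OE cells, and the difference between the ES effects in FDX1-OE and control cells (the interaction).

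The named genes were chosen by a rule. FDX1 was given in each comparison. Then came up to 10 genes with the largest rise and up to 10 with the largest fall among those called, with a mean log2 value of at least 3. Their libraries did not overlap between the groups compared, except for the interaction, where this was not required, and clone, accession and LOC-type names were passed over. For each list described, up to 4 members with the smallest p were added, whether called or not. A gene named outside this rule is said to have been chosen after its values were seen. Metallothioneins, tRNA genes and other near-identical or very short genes are marked as uncertain.

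Each of 38 lists of genes was given a count of members called over all genes and adjusted over the list alone. The lists were protein lipoylation and its enzymes, ferredoxin partners and mitochondrial P450s, copper transport and copper chaperones, metallothioneins, heat shock response, NRF2 targets, integrated stress response (ATF4 targets), endoplasmic reticulum stress (UPR), p53 targets, iron handling, iron-sulfur cluster assembly, haem biosynthesis and haem A, ferroptosis regulators, respiratory complex I, respiratory complexes II to V, mitochondrially encoded mRNAs, tricarboxylic acid cycle, mitochondrial stress and import, glycolysis, hypoxia (HIF targets), cholesterol biosynthesis, fatty acid synthesis and desaturation, S phase and DNA replication, mitosis (G2/M), BCL2 family, B cell and germinal centre identity, plasma cell differentiation, NF-kB targets, interferon-stimulated genes, MHC class II, ribosome biogenesis and MYC targets, cytosolic ribosomal proteins, proteasome, autophagy and lysosome, immediate early genes, T and NK cell markers, myeloid markers and epithelial and fibroblast markers. Set tests were run on the 35 lists with at least 3 members tested, 175 tests over 5 comparisons, with Benjamini-Hochberg adjustment over all of them. The set test was limma's camera with a preset correlation of 0.01, which compares a list with the other genes. It was repeated with an estimated correlation. fry was run beside it, and asks only whether a list's genes move on balance one way, or in either direction. Its directional adjusted p between FDX1-OE and control in ES was 0.00103 for interferon-stimulated genes and 0.000944 for cytosolic ribosomal proteins. With ES in control cells it was 0.00956 and 0.421. As fry does not set a list against other genes, many of which also moved, it does not replace camera. No call of the preset test was kept with an estimated correlation, where the smallest adjusted p = 0.217. This loss does not measure shared variation alone. Fatty acid synthesis with ES in control cells had an estimated correlation of -0.0127, below the preset. Its unadjusted camera p still went from 0.000177 to 0.017. The preset calls assume that genes of a list vary almost independently, and the repeat cannot tell how far they depend on it.

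The fit was tested on simulated data of 12063 genes with the unequal spread of the 4 groups, in which 67 genes were changed 1.5-fold, 67 genes 2-fold and 66 genes 4-fold. Because the spread between replicates was larger in FDX1-OE ES libraries, false calls made up 23.4% of calls for FDX1-OE against control in ES and 21.4% for ES in FDX1-OE cells, against 1.30% for ES in control cells and 4.93% for the interaction. Weighting libraries by the spread of their group, chosen after the data were seen, brought the 4 shares to 6.47%, 4.83%, 4.23% and 5.67%. For FDX1-OE against control in DMSO the share was 0.595% in the planned fit and 6.25% in the weighted fit. For FDX1-OE against control in ES and ES in FDX1-OE cells the planned fit made 205 and 206 simulated calls. The data gave 5008 and 7334. A false share depends on how many genes truly change, so these shares do not carry over to the data. Of the unchanged simulated genes 11.7% and 10.3% had an unadjusted p below 0.05 in these 2 comparisons. Counts from the weighted fit stand beside the counts of the planned fit. In the simulation the planned fit recovered 74.6% to 89.6% of 2-fold changes, depending on the comparison. All 11 raised lists and none (0 of 13) of the unchanged lists were called by the set test. The simulated genes varied independently of each other, so the simulation cannot show how the set test behaves on lists whose genes vary together.

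Alternatives to the planned fit were other scalings, filters, thresholds and pseudocounts, the replicate number as a block, only the 2 groups compared, and leaving out each library in turn. Those added after the data were seen were quantile normalisation, robust variance estimates, removal of trends with transcript length or GC content, protein-coding nuclear genes alone and the weighted fit. Transcript length, GC content and gene type came from GENCODE release 29, which matched 11748 of the 12063 genes tested (97.4%). Length and GC content were those of the longest transcript listed for a symbol, which need not be the one expressed. This is a GRCh38 annotation, while the notes name hg19. A comparison of lists with the 50 coding nuclear genes nearest in control DMSO level, each list's own genes left out, was added after the data were seen. The SE printed with a median over a list comes from the spread between its genes, treated as independent. It holds no error between libraries, unlike the SE of a single gene, which is that of the fit. No measurement column was left out. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.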

Results

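The series asks, by its title, how FDX1 overexpression alters gene expression when WSU-DLCL2 lymphoma cells meet elesclomol. FDX1 is ferredoxin 1, a mitochondrial iron-sulfur protein that passes electrons to other enzymes. Each of the 8 libraries gives FPKM for the same genes. The FPKM sums per library were 449021 ± 2838 (SD, n = 2) in control DMSO, 448084 ± 3348 in FDX1-OE DMSO, 447163 ± 303 in control ES and 405521 ± 3531 in FDX1-OE ES. Genes at 1 FPKM or more numbered 10815 to 10866 in the DMSO libraries, 11225 and 11320 with ES in control cells, and 11868 and 12047 with ES in FDX1-OE cells. The 13 mRNAs of the mitochondrial genome held 17.4% to 17.6% of the FPKM of DMSO libraries, 17.5% and 16.9% with ES in control cells, and 14.7% and 11.9% with ES in FDX1-OE cells. The median absolute log2 difference between the 2 replicates was 0.08 in control DMSO, 0.07 in FDX1-OE DMSO, 0.09 in control ES and 0.16 in FDX1-OE ES. Values below are means ± SD in FPKM with n = 2 in every group.

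FDX1 was the gene that set FDX1-OE cells apart in DMSO. Its level was 10.6 ± 0.266 FPKM (SD, n = 2) in control cells and 57.9 ± 2.72 FPKM (SD, n = 2) in FDX1-OE cells, a rise of 2.35 (SE 0.06, adjusted p = 2.69e-06) on the log2 scale and a ratio of 5.47 in FPKM. FDX1 lies on chromosome 11 from 110429883 to 110464881 on the plus strand (GRCh38, GENCODE release 29). No other gene was called by limma, so 1 of 12063 genes was higher and 0 were lower, while 420 genes had an unadjusted p below 0.05. The planned fit shares its spread with the more variable FDX1-OE ES libraries, which makes it cautious here. In the simulation 2.19% of unchanged genes had an unadjusted p below 0.05 in this comparison. A fit of only the 2 DMSO groups had 898 genes at that level and called 1. The weighted fit had 982 genes at that level and called 4 genes. Over all genes the median log2 fold change was 0.00.

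The pathways that FDX1 serves showed no called member in DMSO, and neither did any other list. Protein lipoylation, the attachment of lipoic acid to mitochondrial enzymes that FDX1 takes part in, had 0 of 14 higher and 0 lower (the same adjusted over the list alone, set test adjusted p = 0.55). Of the 3 ferredoxin partners tested, the reductase FDXR was at 4.86 ± 0.439 in control and 4.9 ± 0.10 FPKM in FDX1-OE cells, and the related ferredoxin FDX2 at 12.5 ± 0.519 and 12.9 ± 0.708 FPKM. Iron-sulfur cluster assembly had 0 of 21 higher and 0 lower (set test adjusted p = 0.692), and respiratory complex I had 0 of 38 higher and 0 lower (set test adjusted p = 0.301). The metallothioneins, small metal-binding proteins, had a median log2 fold change of -0.45 in DMSO with 0 of 5 higher and 0 lower over all genes. Adjusted over the list alone 0 were higher and 3 lower (set test adjusted p = 8.13e-09, adjusted p = 0.217 with an estimated correlation). MT1G was at 2.3 ± 0.748 in control and 0.52 ± 0.148 FPKM in FDX1-OE cells and MT2A at 29.3 ± 3.77 and 22.7 ± 4.77 FPKM. Metallothioneins are near-identical copies, so their separate values are uncertain throughout. DNAJB11, a chaperone of the endoplasmic reticulum, was at 36.8 ± 2.1 and 29.5 ± 0.359 FPKM (log2 -0.31, adjusted p = 0.999). Its list of endoplasmic reticulum stress genes had 0 of 18 higher and 0 lower (0 and 1 adjusted over the list alone, set test adjusted p = 0.000907, adjusted p = 0.297 with an estimated correlation).

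**Figure D1:**
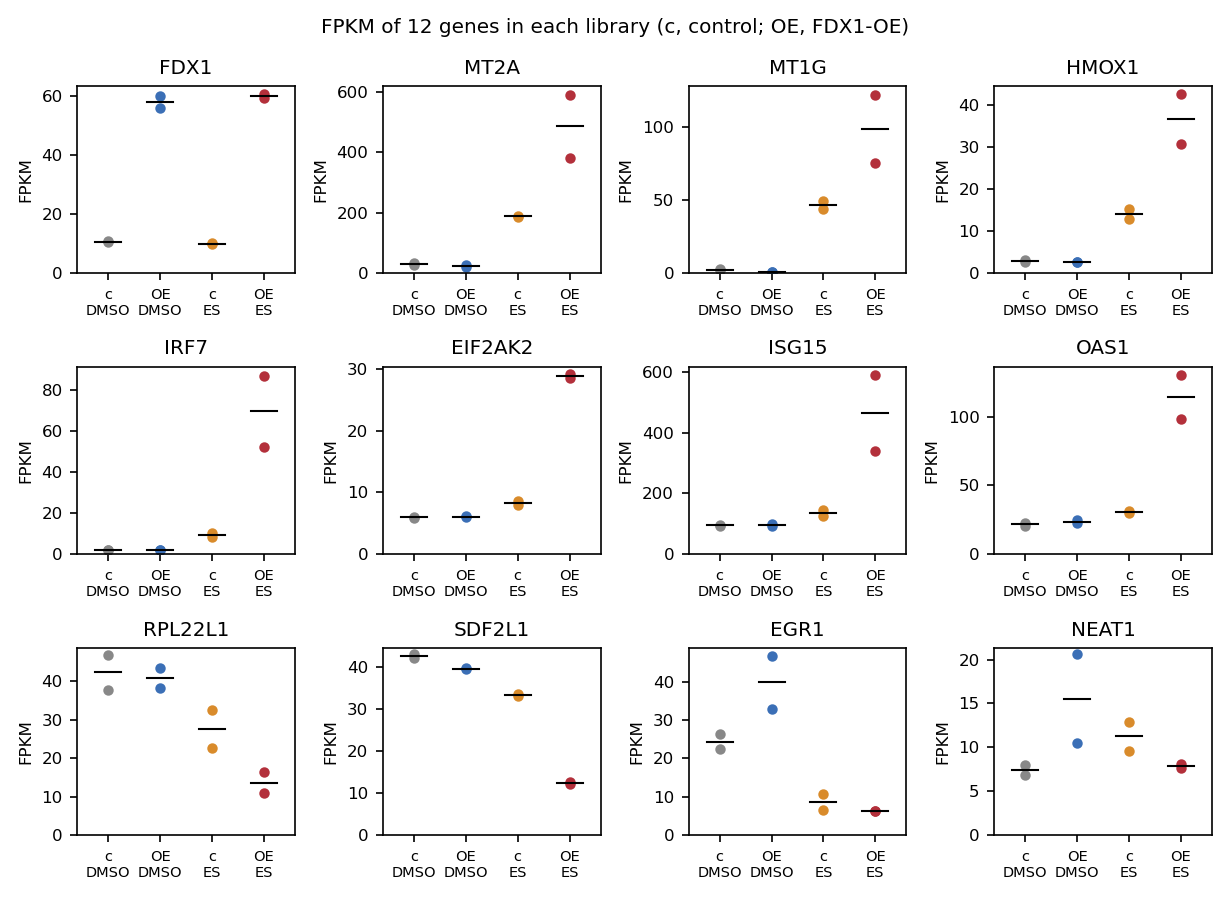
FPKM of 12 genes (y axis, linear from 0) in each of the 8 libraries (points) by group (x axis), with the mean of the 2 libraries as a line. FDX1 is raised in the 4 FDX1-OE libraries, and metallothioneins, HMOX1, IRF7 and EIF2AK2 are highest in the 2 FDX1-OE ES libraries.

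Elesclomol alone, in control cells, raised metallothioneins, HMOX1 and interferon-stimulated genes. Among called genes with a mean log2 value of at least 3 and no overlap between the groups, the rule for the rankings below, the largest rises included MT1H (4.59), MT1G (3.87), MT-TK (2.88), MT2A (2.64), MT1F (2.06), HMOX1 (1.96), MT-TR (1.87), IRF7 (1.83) and MT-TM (1.54), as log2 fold changes. MT2A went from 29.3 ± 3.77 to 188 ± 2.71 FPKM (adjusted p = 0.000825). HMOX1, the enzyme that breaks down haem, went from 2.85 ± 0.223 to 14.0 ± 1.71 FPKM (adjusted p = 0.000825). All 5 metallothioneins tested rose (the same adjusted over the list alone, median log2 2.64, set test adjusted p = 1.84e-09, adjusted p = 0.217 with an estimated correlation), MT1X among them (1.17, adjusted p = 0.000253). IRF7, a transcription factor that switches on interferon genes, went from 1.83 ± 0.0892 to 9.11 ± 1.3 FPKM. MT-TK, MT-TR and MT-TM are mitochondrial tRNA genes, whose short models make their FPKM uncertain.

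Of 31 interferon-stimulated genes 21 rose and 0 fell (28 and 0 adjusted over the list alone). Their median log2 fold change was 0.76 above that of all genes (set test adjusted p = 1.06e-16, adjusted p = 0.304 with an estimated correlation). MX1, an antiviral GTPase, rose from 0.0284 ± 0.0102 to 5.66 ± 0.437 FPKM (2.69, adjusted p = 0.000622), IFI6 by 2.85 and IFI44 by 1.10. ATF4 targets of the integrated stress response, which slows translation and raises amino acid genes, had 9 of 26 higher and 0 lower (15 and 1 adjusted over the list alone, set test adjusted p = 0.00349, adjusted p = 0.31 with an estimated correlation). Among them PCK2, a mitochondrial gluconeogenic enzyme, rose by 1.75, the glutathione-degrading enzyme CHAC1 by 1.84, the tRNA synthetase WARS1 by 0.78 and the transcription factor ATF5 by 0.71. NRF2 targets, genes of the antioxidant response, had 5 of 19 higher and 0 lower (5 and 1 adjusted over the list alone, set test adjusted p = 0.301), and the sign of the list's median turned under median-ratio scaling. NQO1 (1.11, adjusted p = 0.00978) and the ferritin chains FTH1 (0.81, adjusted p = 0.0105) and FTL (0.49, adjusted p = 0.0141) rose with HMOX1.

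The 10 largest falls ranked in this way with ES in control cells were EGR1 (-1.42), DBNL (-0.95), ZFP36L1 (-0.89), DUSP2 (-0.83), SGK1 (-0.79), MT-TD (-0.74), MT-TE (-0.67), YRDC (-0.65), RGS16 (-0.63) and MT-ND5 (-0.61). EGR1, a transcription factor induced by growth signals, went from 24.3 ± 2.77 to 8.66 ± 2.92 FPKM, and DUSP2, a phosphatase of MAP kinases, from 72.5 ± 4.71 to 40.5 ± 3.87 FPKM. Immediate early genes had 0 of 16 higher and 3 lower (1 and 4 adjusted over the list alone, set test adjusted p = 9.11e-07, adjusted p = 0.304 with an estimated correlation). NF-kB targets had 2 of 20 higher and 3 lower (2 and 4 adjusted over the list alone, set test adjusted p = 2.63e-05, adjusted p = 0.31 with an estimated correlation). The chemokine CCL22 rose (0.77, adjusted p = 0.0124), while NFKBIA, the inhibitor of NF-kB, fell (-0.49, adjusted p = 0.0191), as did CD83 (-0.39, adjusted p = 0.0372) and IER2 (-0.60, adjusted p = 0.0276). Ribosome biogenesis genes had 0 of 27 higher and 4 lower (0 and 14 adjusted over the list alone, set test adjusted p = 1.84e-15, adjusted p = 0.217 with an estimated correlation). NOP16 (-0.41, adjusted p = 0.0226), PA2G4 (-0.36, adjusted p = 0.0353), the nucleolin gene NCL (-0.32, adjusted p = 0.0387) and NOP56 (-0.24, adjusted p = 0.0397) fell. Cholesterol biosynthesis had 0 of 23 higher and 4 lower (the same adjusted over the list alone, set test adjusted p = 1.05e-08, adjusted p = 0.217 with an estimated correlation). INSIG1, a sterol sensor (-0.45, adjusted p = 0.022), and the enzyme genes DHCR7 (-0.26, adjusted p = 0.0422) and FDPS (-0.23, adjusted p = 0.045) fell. FDX1 was at 10.6 ± 0.266 FPKM in DMSO and 9.95 ± 0.108 FPKM in ES (log2 -0.08, adjusted p = 0.448).

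In all, 934 genes were called with ES in control cells, 813 higher and 121 lower (3305 with an unadjusted p below 0.05), and 70 rose and 5 fell by at least 1 on the log2 scale. The weighted fit called 2523 genes (2062 higher and 461 lower), all 934 among them. The count fell widely without any 1 control or FDX1-OE DMSO library and rose without either FDX1-OE ES library. FDX1-OE libraries do not enter this comparison, so the count hangs on the estimate of spread and on genes near the threshold. It cannot show that a particular library decides. The median log2 fold change of all genes was 0.09 with all libraries, 0.11 without control ES replicate 1 and 0.08 without control ES replicate 2. Each of these 10 falls missed the threshold under some alternative, with a highest adjusted p of 0.0952 for EGR1, 0.181 for DBNL, 0.0608 for ZFP36L1 and DUSP2, 0.112 for SGK1, 0.133 for MT-TD, 0.0659 for MT-TE, 0.201 for YRDC, 0.146 for RGS16 and 0.22 for MT-ND5. Their lowest lay between 0.00109 for DUSP2 and 0.011 for DBNL, and IRF7 and MT1F reached 0.0686 and 0.0532. Of the 31 interferon-stimulated genes 4 were called without control ES replicate 2, 11 without control ES replicate 1, and 9 and 8 without control DMSO replicates 1 and 2, and of the ATF4 targets 1, 4, 4 and 4. With quantile normalisation the interferon-stimulated genes had 13 higher and 0 lower, ATF4 targets 5 higher and 0 lower and ribosome biogenesis 0 higher and 0 lower, against 0 higher and 14 lower with median-ratio scaling. Over the scalings the share of called genes that were higher moved from 87.0% to 52.5% with median-ratio scaling and 74.5% with quantile normalisation.

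In FDX1-OE cells elesclomol raised metallothioneins, interferon-stimulated genes and haem oxygenase. At a mean log2 value of at least 3 the largest rises included MT1H (6.30), MT1G (6.0), IRF7 (4.53), MT-TK (4.39), MT2A (4.35), HMOX1 (3.37), MT-TR (3.33), MT1F (3.33) and MT-TM (3.03). MT2A went from 22.7 ± 4.77 to 486 ± 148 FPKM (SD, n = 2). IRF7 went from 1.95 ± 0.141 to 69.5 ± 24.5 FPKM and HMOX1 from 2.6 ± 0.0891 to 36.6 ± 8.41 FPKM, each of these with an adjusted p of at most 4.59e-06. MT1H was at 0.0508 ± 0.0718 FPKM in DMSO, with 1 of its 2 libraries listed at 0, and at 82.9 ± 20.3 FPKM in ES. FDX1 itself was at 57.9 ± 2.72 and 60.1 ± 0.977 FPKM (log2 0.05, adjusted p = 0.502), and its sign turned under median-ratio scaling (-0.23, adjusted p = 0.0159, with 0.0078 to 0.964 over all alternatives).

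All 31 interferon-stimulated genes rose in FDX1-OE cells, with a median log2 fold change of 3.48 (set test adjusted p = 2.84e-15, adjusted p = 0.31 with an estimated correlation). MX1 went from 0.101 ± 0.0352 to 101 ± 33.0 FPKM (6.5, adjusted p = 1.3e-06), IFIT3 from 0.0399 ± 0.0149 to 18.5 ± 3.91 FPKM and IFI44 from 0.0359 ± 0.0508 to 16.8 ± 1.95 FPKM. Markers of T and NK cells and of myeloid cells were measured beside them. TRAC, the T-cell receptor constant region, was at 83.2 ± 3.22 FPKM in DMSO and 80.9 ± 0.997 FPKM in ES (log2 -0.04, adjusted p = 0.562). The myeloid marker AIF1 rose by 0.64 to 3.61 ± 1.02 FPKM. All 5 metallothioneins rose (median log2 4.35, set test adjusted p = 0.00036, adjusted p = 0.217 with an estimated correlation). ATF4 targets had 21 of 26 higher and 1 lower (22 and 1 adjusted over the list alone, set test adjusted p = 0.000383, adjusted p = 0.291 with an estimated correlation), with ATF3 (2.66), PCK2 (2.65), WARS1 (1.98) and ATF5 (1.68) higher. NRF2 targets had 10 of 19 higher and 3 lower (the same adjusted over the list alone, set test adjusted p = 0.437), and 7 higher and 7 lower with median-ratio scaling. NQO1 (2.12), the cystine transporter SLC7A11 (1.54) and FTH1 (1.53) rose. NF-kB targets had 15 of 20 higher and 2 lower (16 and 2 adjusted over the list alone, set test adjusted p = 0.041, adjusted p = 0.685 with an estimated correlation), and 9 higher and 2 lower with median-ratio scaling. CCL22 (2.39), the lymphocyte transcription factor IRF4 (1.57), CD44 (1.30) and TRAF1 (1.07) were higher.

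Genes for making ribosomes fell together in FDX1-OE cells with ES. Of 73 cytosolic ribosomal protein genes 0 rose and 66 fell (the same adjusted over the list alone). Their median log2 fold change less that of all genes was -0.75 (set test adjusted p = 1.17e-36, adjusted p = 0.217 with an estimated correlation). The list's own median lay below 0 under every scaling, though quantile normalisation left 7 higher and 34 lower. Abundant genes in general moved the same way, and against the 50 coding genes nearest in level the median difference was -0.10 (SE 0.04) for ribosomal proteins and -0.51 (SE 0.08) for ribosome biogenesis genes. RPL10A went from 885 ± 12.9 to 459 ± 11.6 FPKM (-0.95, adjusted p = 1.04e-05) and RPS14 from 344 ± 15.5 to 172 ± 6.7 FPKM (-1.0, adjusted p = 2.76e-05). Of 27 ribosome biogenesis genes 26 fell (set test adjusted p = 1.22e-19, adjusted p = 0.217 with an estimated correlation). They included NOP16 (-1.43), RRS1 (-1.06), BOP1 (-0.87) and NME1 (-0.87). At a mean log2 value of at least 3 the 10 largest falls were TOMM6 (-3.48), EGR1 (-2.46), SENP3-EIF4A1 (-2.40), MIR4442 (-1.97), FOS (-1.67), SDF2L1 (-1.60), DUSP2 (-1.56), RPL22L1 (-1.54), DBNL (-1.50) and SLC17A9 (-1.47). TOMM6, part of the protein entry gate of mitochondria, had an adjusted p between 0.00187 and 0.151 over the alternatives. The read-through gene SENP3-EIF4A1 and the microRNA gene MIR4442 overlap other genes, so these 3 values are uncertain, and MIR4442 was at -1.31 without FDX1-OE ES replicate 2. SDF2L1, a protein of the endoplasmic reticulum, went from 39.5 ± 0.211 to 12.3 ± 0.331 FPKM, and SLC17A9, a nucleotide transporter, from 20.5 ± 1.32 to 6.77 ± 0.818 FPKM.

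Glycolysis and respiratory chain genes held more falls than rises under each scaling. Glycolysis had 3 of 19 higher and 15 lower (the same adjusted over the list alone, set test adjusted p = 6.21e-09, adjusted p = 0.229 with an estimated correlation). The enzyme genes PGK1 (-0.82), HK2 (-1.03), ENO1 (-0.73) and GAPDH (-0.65) fell. Respiratory complex I had 5 of 38 higher and 18 lower (5 and 19 adjusted over the list alone, set test adjusted p = 4.45e-08, adjusted p = 0.25 with an estimated correlation). NDUFB8 (-0.92), NDUFA13 (-0.56) and NDUFS5 (-0.63) were lower. Respiratory complexes II to V had 2 of 38 higher and 19 lower (the same adjusted over the list alone, set test adjusted p = 1.06e-10, adjusted p = 0.217 with an estimated correlation). ATP5F1D (-1.32), ATP5MC1 (-1.11) and COX6B1 (-0.80) were lower. Cholesterol biosynthesis had 0 of 23 higher and 13 lower (the same adjusted over the list alone, set test adjusted p = 1.46e-09, adjusted p = 0.217 with an estimated correlation). With median-ratio scaling complexes II to V had 1 higher and 34 lower and cholesterol biosynthesis 0 higher and 20 lower, and with equal FPKM totals complexes II to V had 3 higher and 12 lower. The enzyme genes FDFT1 (-0.72), DHCR7 (-0.70) and FDPS (-0.69) fell. Fatty acid synthesis had 0 of 11 higher and 6 lower (the same adjusted over the list alone, set test adjusted p = 0.00194, adjusted p = 0.217 with an estimated correlation) and 4 higher and 3 lower with equal FPKM totals, with FASN, the fatty acid synthase, at -1.23, its regulator SREBF1 at -0.81 and the desaturase SCD at -1.06. The heat shock response had 6 of 20 higher and 12 lower (7 and 12 adjusted over the list alone, set test adjusted p = 0.000369, adjusted p = 0.31 with an estimated correlation). The chaperone genes HSPE1 (-1.21), AHSA1 (-0.94) and FKBP4 (-0.98) fell, while the collagen chaperone SERPINH1 rose (1.91). Mitochondrial stress and import genes had 2 of 17 higher and 10 lower (the same adjusted over the list alone, set test adjusted p = 0.000648, adjusted p = 0.217 with an estimated correlation). ATF5 rose, while HSPE1, TIMM23 (-0.42) and TOMM40 (-0.59) fell.

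RNAs of the mitochondrial genome moved apart with ES in FDX1-OE cells. Of 13 mitochondrially encoded mRNAs 1 rose and 8 fell (the same adjusted over the list alone, set test adjusted p = 7.97e-06, adjusted p = 0.49 with an estimated correlation). Quantile normalisation left 5 higher and 5 lower. MT-CO1 (-0.99), MT-CO2 (-0.89) and MT-ND5 (-1.41) fell, and MT-ND2 rose (0.96) from 2676 ± 61.8 to 5245 ± 745 FPKM. In control cells with ES the list had 3 of 13 higher and 1 lower (5 and 5 adjusted over the list alone, set test adjusted p = 0.164), and the sign of its median turned under quantile normalisation. Of 22 mitochondrial tRNA genes, a group chosen after its values were seen, 11 rose and 10 fell in FDX1-OE cells, against 6 and 2 in control cells. MT-TK (4.39), MT-TR (3.33), MT-TM (3.03) and MT-TA (2.29) rose, while MT-TT (-1.42), MT-TH (-1.26) and MT-TS1 (-1.04) fell.

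**Figure D2:**
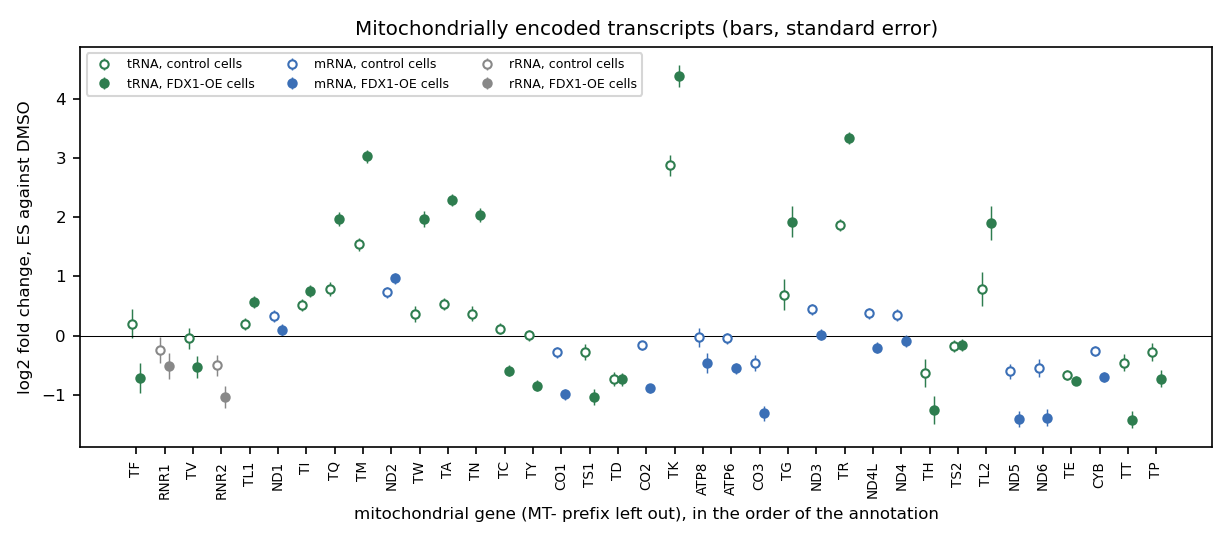
Log2 fold change with ES against DMSO (y axis) of each gene of the mitochondrial genome in the order of the annotation (x axis), in control cells (open points) and FDX1-OE cells (filled points), with the SE of the fit as bars. The tRNA gene MT-TK stands highest at 4.39 in FDX1-OE cells, and MT-TT lies at -1.42.

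Called genes of copper and FDX1 pathways went in both directions with ES in FDX1-OE cells, as genes in general did. Over all genes 5682 of 12063 were higher and 1652 lower. In each list below the share called higher was below that of all genes, and no set test was called. Copper transport and chaperone genes had 6 of 14 higher and 3 lower (the same adjusted over the list alone, set test adjusted p = 0.384). SLC30A1, a zinc exporter, rose (0.94), as did COX19 (0.73) and COMMD1 (0.56), and the superoxide dismutase SOD1 fell (-0.51). Protein lipoylation had 5 of 14 higher and 1 lower (the same adjusted over the list alone, set test adjusted p = 0.847). DLST, a lipoylated enzyme subunit, rose (0.53), and the lipoylated glycine cleavage protein gene GCSH fell (-0.66). Iron-sulfur cluster assembly had 8 of 21 higher and 2 lower (7 and 1 adjusted over the list alone, set test adjusted p = 0.692). The scaffold gene ISCU rose (0.60). Of the ferredoxin partners FDXR rose (0.45, adjusted p = 0.0206), 1 of 3 tested (the same adjusted over the list alone, set test adjusted p = 0.814). With median-ratio scaling copper genes had 4 higher and 6 lower, lipoylation 1 higher and 6 lower, cluster assembly 1 higher and 8 lower and ferredoxin partners 0 higher and 0 lower. The signs of these 4 medians turned under at least 1 other scaling, and for copper, lipoylation and cluster assembly the set test pointed lower while the median lay above 0.

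In all, 7334 genes were called with ES in FDX1-OE cells, 5682 higher and 1652 lower (7834 with an unadjusted p below 0.05), and 749 rose and 89 fell by at least 1 on the log2 scale. The weighted fit called 6012 genes (4671 higher and 1341 lower), 6004 of them shared. Median-ratio scaling called 3069 genes higher and 3287 lower, and the median log2 fold change of all genes was 0.25 as deposited, 0.37 with equal FPKM totals and near 0 with median-ratio scaling. Across 10161 coding nuclear genes the change ran against abundance (Spearman's rho -0.451), with a median of 0.55 in the least and -0.07 in the most abundant of 5 equal groups. Against genes of like level the median difference was -0.20 (SE 0.12) for glycolysis, -0.22 (SE 0.06) for respiratory complex I, -0.06 (SE 0.08) for complexes II to V, -0.41 (SE 0.09) for cholesterol biosynthesis and 2.47 (SE 0.23) for interferon-stimulated genes.

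The effect of ES was compared between the 2 kinds of cell, which share no library. Across 12063 genes the log2 fold changes had a Pearson's r of 0.707 and a Spearman's rho of 0.698, where genes are not independent replicates. Of the 813 genes higher in control cells 777 were also higher in FDX1-OE cells (383 if the calls were independent), and of 121 lower genes 104 were also lower (16.6 if independent). Only 8 genes were called in opposite directions. Of the 934 genes, 910 had the same sign, with a median absolute log2 fold change of 0.52 in control cells and 0.90 in FDX1-OE cells. Both effects ran against abundance across coding nuclear genes (Spearman's rho -0.347 in control and -0.451 in FDX1-OE cells). The median of all genes was 0.09 and 0.25. The counts under independence do not allow for these shared trends, whose part in the agreement was not tested.

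**Figure D3:**
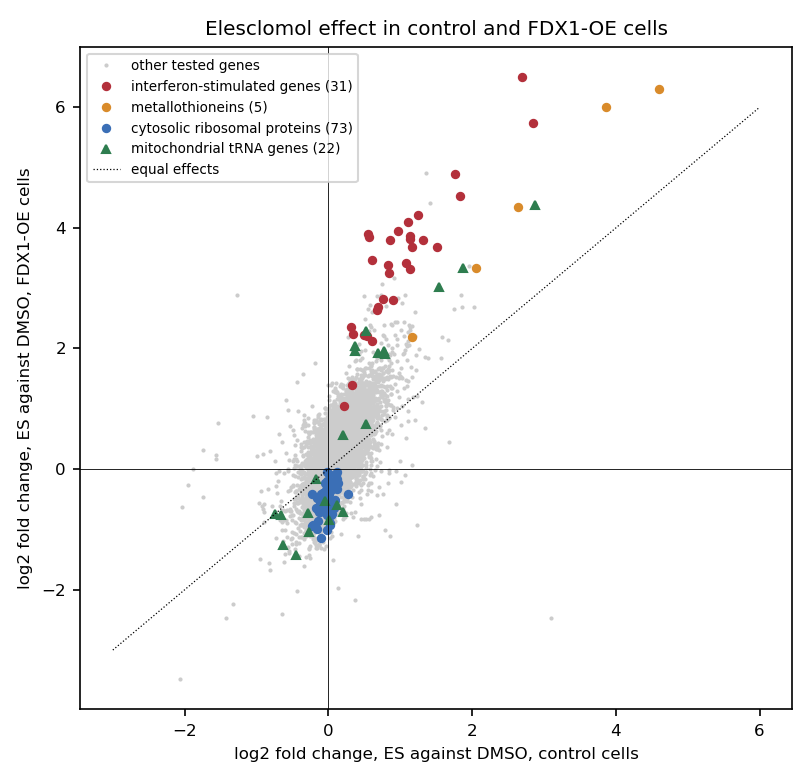
Log2 fold change with ES in control cells (x axis) against that in FDX1-OE cells (y axis), 1 point per gene tested, with 4 gene groups in colour and a dotted line for equal effects. Pearson's r across genes was 0.707, and IRF7 lies at 1.83 and 4.53.

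FDX1-OE cells were set against control cells in ES, the comparison named by the title. FDX1 was at 9.95 ± 0.108 FPKM (SD, n = 2) in control and 60.1 ± 0.977 FPKM (SD, n = 2) in FDX1-OE cells (2.48, adjusted p = 1.71e-06). At a mean log2 value of at least 3 the other largest rises included interferon genes and 1 tRNA gene: IRF7 (2.76), OAS3 (2.14), PLSCR1 (1.92), OAS1 (1.85), ISG15 (1.71), SP110 (1.71), MT-TK (1.70) and EIF2AK2 (1.68). ISG15, a ubiquitin-like modifier, was at 137 ± 13.8 in control and 466 ± 178 FPKM in FDX1-OE cells, and EIF2AK2, a kinase that senses viral RNA, at 8.32 ± 0.444 and 28.8 ± 0.489 FPKM. All 31 interferon-stimulated genes were higher (median log2 2.57, set test adjusted p = 3.08e-20, adjusted p = 0.293 with an estimated correlation). Among them were IFIT3 (2.98), OAS2 (2.96) and IFI44 (2.96). NF-kB targets had 18 of 20 higher and 0 lower (the same adjusted over the list alone, set test adjusted p = 3.54e-05, adjusted p = 0.31 with an estimated correlation). CCL22 (1.44), NFKBIA (0.89), TNFAIP3 (0.85) and CD83 (0.77) were higher. ATF4 targets had 19 of 26 higher and 0 lower (20 and 0 adjusted over the list alone, set test adjusted p = 5.58e-05, adjusted p = 0.25 with an estimated correlation). ATF3 (2.05), WARS1 (1.13), ATF5 (0.98) and the asparagine synthetase gene ASNS (0.86) were higher.

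All 5 metallothioneins were higher in FDX1-OE than in control cells given ES (median log2 1.03, set test adjusted p = 0.0182, adjusted p = 0.306 with an estimated correlation), MT2A at 188 ± 2.71 and 486 ± 148 FPKM, though 2 were called without control ES replicate 1. NRF2 targets had 10 of 19 higher and 3 lower (the same adjusted over the list alone, set test adjusted p = 0.405), with HMOX1 (1.31) and SLC7A11 (0.93) higher, and the sign of the list's median turned under median-ratio scaling. At a mean log2 value of at least 3 the 10 largest falls were SENP3-EIF4A1 (-1.87), MIR4442 (-1.41), MT-TF (-1.38), SDF2L1 (-1.36), SNORD104 (-1.13), CORO1A (-1.13), SLC17A9 (-1.12), SNHG4 (-1.12), DDN (-1.12) and NOP16 (-1.10). CORO1A, an actin-binding protein of leukocytes, was at 288 ± 33.2 in control and 131 ± 7.67 FPKM in FDX1-OE cells. Over the alternatives the adjusted p ranged from 0.00221 to 0.119 for SENP3-EIF4A1 and from 0.00586 to 0.195 for MIR4442, whose difference was -0.75 without FDX1-OE ES replicate 2. Ribosomal protein genes had 0 of 73 higher and 66 lower (0 and 69 adjusted over the list alone, set test adjusted p = 5.5e-41, adjusted p = 0.217 with an estimated correlation), with RPS27A (-0.73) and RPL3 (-0.65) lower, and 4 higher and 30 lower after quantile normalisation. Ribosome biogenesis had 0 of 27 higher and 24 lower (0 and 26 adjusted over the list alone, set test adjusted p = 4.44e-19, adjusted p = 0.217 with an estimated correlation). Glycolysis had 1 of 19 higher and 13 lower (3 and 14 adjusted over the list alone, set test adjusted p = 1.84e-09, adjusted p = 0.217 with an estimated correlation). Respiratory complexes II to V had 1 of 38 higher and 25 lower (1 and 28 adjusted over the list alone, set test adjusted p = 2.65e-15, adjusted p = 0.217 with an estimated correlation). Mitochondrially encoded mRNAs had 0 of 13 higher and 11 lower (0 and 12 adjusted over the list alone, set test adjusted p = 6.41e-09, adjusted p = 0.336 with an estimated correlation). MT-CO1 (-0.71) and MT-CO2 (-0.69) were lower. Quantile normalisation left 1 higher and 3 lower among these mRNAs and 0 higher and 8 lower in glycolysis, and equal FPKM totals 1 higher and 13 lower in complexes II to V. Against genes of like level the median difference was -0.13 (SE 0.03) for ribosomal proteins, -0.34 (SE 0.06) for ribosome biogenesis, -0.13 (SE 0.09) for glycolysis and -0.17 (SE 0.06) for complexes II to V. For mitochondrially encoded mRNAs it was -0.09 (SE 0.11), but the reference holds nuclear genes only. Too few of those reach the levels of most of these mRNAs, up to 13312 FPKM in control DMSO. The value therefore cannot tell whether abundance accounts for their fall.

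**Figure D4:**
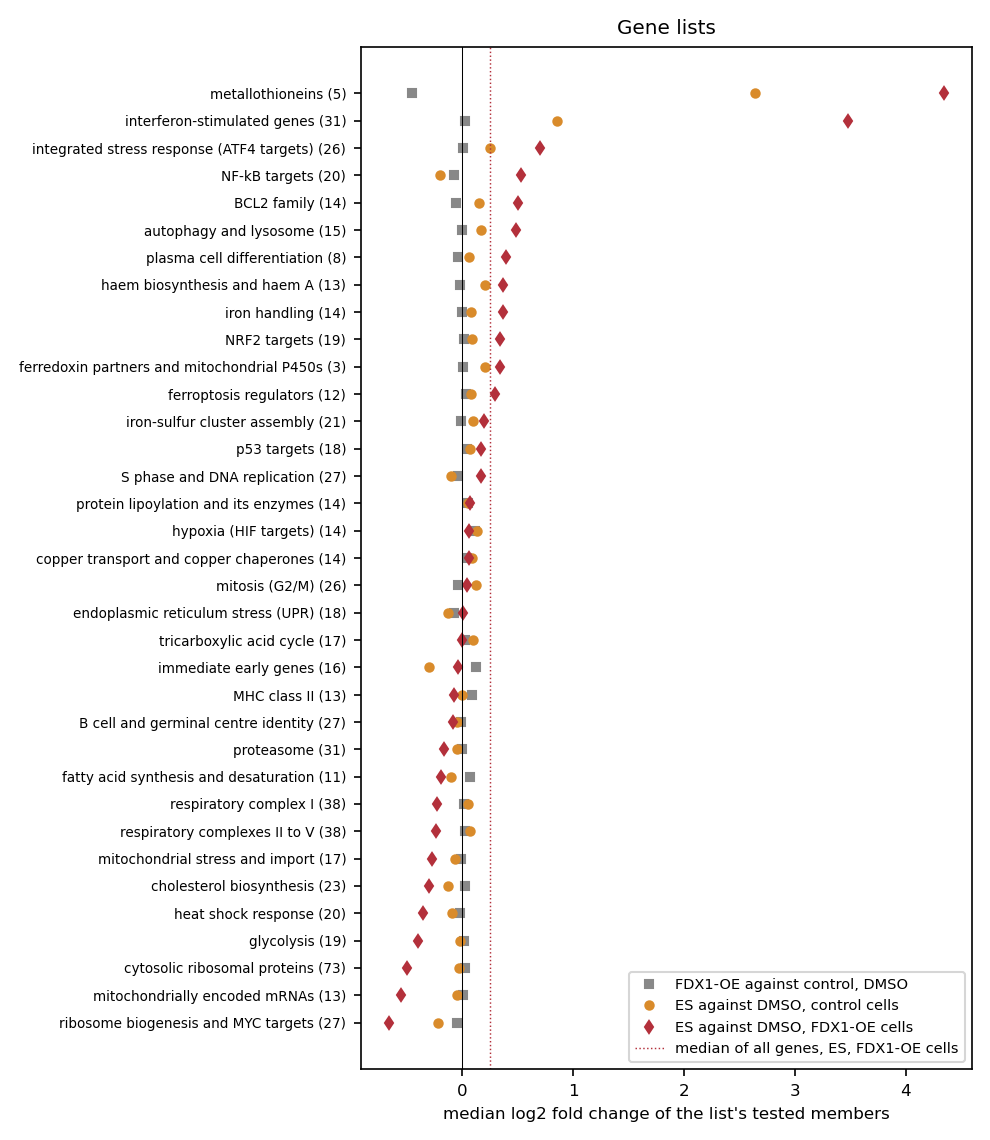
Median log2 fold change (x axis) of the 35 gene lists with at least 3 members tested (y axis) in 3 comparisons (points), with the median of all genes with ES in FDX1-OE cells as a dotted line. Lists near 0 change sign under other scalings, while interferon-stimulated genes and metallothioneins do not: interferon-stimulated genes reach 3.48 with ES in FDX1-OE cells and 0.85 in control cells.

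In all, 5008 genes were called between FDX1-OE and control cells in ES, 3757 higher and 1251 lower (6190 with an unadjusted p below 0.05), and 202 were higher and 20 lower by at least 1 on the log2 scale. The weighted fit called 3026 (2174 higher and 852 lower), all among the 5008, and a fit of only the 2 groups called 3117. The count was 2499 without control ES replicate 1 and 3203 without control ES replicate 2. Median-ratio scaling called 1818 higher and 2218 lower. Across genes the effects of FDX1-OE in DMSO and in ES, which share no library, had a Pearson's r of 0.03 and a Spearman's rho of 0.05.

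The interaction tests whether the ES effect itself differed between FDX1-OE and control cells. It was larger in FDX1-OE cells for IRF7 (2.70), MT1G (2.13), SP110 (2.00), OAS3 (2.00), PLSCR1 (1.81), MT-TA (1.76), OAS1 (1.72), MT1H (1.71) and MT2A (1.70), as differences of log2 fold changes. For metallothioneins part of the difference lay in DMSO. Their median log2 fold change in FDX1-OE against control cells was -0.45 in DMSO, with 0 of 5 called, and 1.03 in ES. FDX1 had an interaction of 0.13 (adjusted p = 0.325). All 31 interferon-stimulated genes and all 5 metallothioneins had a larger ES effect in FDX1-OE cells. For the first the set test gave adjusted p = 1.66e-24, adjusted p = 0.253 with an estimated correlation, and for the second adjusted p = 0.000648, adjusted p = 0.229 with an estimated correlation. So did 14 of 20 NF-kB targets (17 and 0 adjusted over the list alone, set test adjusted p = 4.24e-06, adjusted p = 0.304 with an estimated correlation). The same held for 14 of 26 ATF4 targets (18 and 0 adjusted over the list alone, set test adjusted p = 5.29e-05, adjusted p = 0.25 with an estimated correlation), with 8 higher and 1 lower under median-ratio scaling. CCL22 differed by 1.62, ATF3 by 2.10 and HMOX1 by 1.41. The difference was negative for 61 of 73 ribosomal protein genes (0 and 64 adjusted over the list alone, set test adjusted p = 4.89e-42, adjusted p = 0.217 with an estimated correlation), such as RPL10A (-0.72), and against genes of like level the median difference was -0.17 (SE 0.04). It was negative for 15 of 27 ribosome biogenesis genes (0 and 20 adjusted over the list alone, set test adjusted p = 9.47e-17, adjusted p = 0.217 with an estimated correlation), such as NOP16 (-1.02), with 0 higher and 8 lower under equal FPKM totals. It was also negative for SDF2L1 (-1.26), the uncoupling protein gene UCP2 (-1.14), SLC17A9 (-1.22), SSR4 (-1.14) and the noncoding RNA NEAT1 (-1.35), whose FDX1-OE DMSO libraries held 10.5 and 20.6 FPKM (-0.90 without FDX1-OE DMSO replicate 2).

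The interaction was called for 2291 genes, 1681 positive and 610 negative (4370 with an unadjusted p below 0.05). The weighted fit called 1921 (1321 positive and 600 negative), 1851 of them shared. The count was 693 and 732 without control DMSO replicates 1 and 2, 623 and 535 without FDX1-OE DMSO replicates 1 and 2, 615 and 988 without control ES replicates 1 and 2, and 3462 without FDX1-OE ES replicate 1. In the same order and up to control ES replicate 2, the negative calls among cytosolic ribosomal proteins were 26, 25, 26, 24, 27 and 27, those higher among NF-kB targets 7, 10, 8, 6, 6 and 11, and 3 metallothioneins were called without control ES replicate 1. Quantile normalisation left 1 higher and 18 lower among the ribosomal proteins, median-ratio scaling called 705 genes positive and 1134 negative, and the median of all genes was 0.15 as deposited and 0.27 with equal FPKM totals.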

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

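All tests of explanations in this part were chosen after the result was seen, except the test of the most abundant genes, written before. The results here are differences between the ES effects of FDX1-OE and control cells, found by the interaction test. It was called for 2291 genes, with differences in log2 fold change of 2.70 for IRF7, 2.13 for MT1G, 2.00 for SP110, 2.00 for OAS3, 1.81 for PLSCR1, 1.76 for MT-TA, 1.72 for OAS1, 1.71 for MT1H and 1.70 for MT2A. The most negative were -1.35 for NEAT1, -1.26 for SDF2L1, -1.22 for SLC17A9, -1.21 for MICOS13, -1.15 for SNHG4, -1.15 for CCDC78, -1.14 for UCP2, -1.14 for SSR4, -1.13 for SLC27A5 and -1.13 for SNORD104. NEAT1 had 20.6 FPKM in FDX1-OE DMSO replicate 2 and 10.5 FPKM in replicate 1, and its difference was -0.90 without replicate 2. MT1G was at 1.77 and 2.83 FPKM in control DMSO and 0.625 and 0.416 FPKM in FDX1-OE DMSO. Part of its difference therefore lay in DMSO. Over the alternatives the highest adjusted p was 0.154 for NEAT1, 0.116 for SNORD104, 0.084 for SNHG4, 0.0646 for MICOS13, 0.0959 for MT1H and 0.059 for MT2A, which missed the threshold there.

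All 31 interferon-stimulated genes rose with ES in FDX1-OE cells, and all differed from control cells in the interaction, while in DMSO the median difference between the 2 kinds of cell was 0.03 with 0 called. Cells of another type are argued against: of 30 T, NK and myeloid markers with a value 3 reached 1 FPKM in any library, and the largest rise was 1.67 FPKM (AIF1) against 67.5 FPKM for IRF7, a comparison added after that test had been run. For ES in FDX1-OE cells the calls were kept with each library left out in turn, but this cannot exclude a single deciding library. Control libraries do not enter that comparison, and leaving out an FDX1-OE ES replicate takes the most variable group out of the shared spread. Both FDX1-OE ES libraries exceeded both FDX1-OE DMSO libraries for IRF7, EIF2AK2, ISG15 and OAS1. IRF7, for instance, was at 52.2 and 86.8 FPKM against 2.05 and 1.85 FPKM. Whether interferon beta transcription lay behind the rise of the list cannot be told, since IFNB1 did not pass the filter. It was listed at 0 in the 4 DMSO libraries and 1 control ES library and at 0.0373 FPKM in the other. In FDX1-OE ES it was at 0.127 and 0.957 FPKM. A candidate explanation, left open, is a stronger interferon response in ES-treated cells with more FDX1, a hypothesis found and tested on the same data.

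Ribosomal protein genes fell with ES in FDX1-OE cells (66 of 73) and differed from control cells in the interaction (61 of 73). The length of the longest listed transcript is argued against as the whole cause, since the median difference from genes of like length was -0.68 (SE 0.04, 73 genes). The length of the transcript expressed was not tested. Those genes were not matched in level, so the difference also holds any trend with abundance. The 50 most abundant genes held 26.3% and 23.8% of the FPKM in FDX1-OE ES libraries, against 31.9% and 32.3% in FDX1-OE DMSO. They thus took up no larger share with ES. With libraries rescaled to fragments outside the 50 most abundant genes the list's median was -0.59 (SE 0.03) and that of all genes 0.17. As that share fell, the rescaling could only lower the list, so it decides nothing. Abundance stays open for most of the fall, since the median difference from coding genes of like level was -0.10 (SE 0.04), or -0.04 with the ribosomal proteins outside the list left among them. Scaling stays open too: the highest median over the scalings was -0.17, with quantile normalisation, where 34 of the 73 were called lower and 7 higher, and a biological fall with FDX1 and ES stays open.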

How the results depend on the processing

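Among the settings tried, quantile normalisation, robust variances, length and GC corrections, coding genes alone and the weighted fit were tests chosen after the data were seen. The planned count-based test and the thinning to equal depth were not run, since the files hold no counts. With libraries left in, 1221 results on named genes stayed on their side of the threshold without a called value changing sign, 74 lost the call, 1 gained it and 3 reversed, changing sign while called in at least 1 of the 2 fits. For gene lists the numbers were 1297, 161, 96 and 21. Among the 1221 and 1297, 3 and 88 changed sign while called in neither fit, the lists from medians as high as 0.34. The cause of the changes below was not tested unless the alternative itself tests fewer genes or libraries or sets a stricter threshold. A replicate block changed no count of called genes by more than 1.5 times, and deviations from group means did not pair by replicate number (correlations of -0.05 to 0.08).

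For FDX1-OE against control in DMSO the count of 1 became 3 without a filter, 2 with a pseudocount of 0.1 and no filter, 2 with robust variances and 4 in the weighted fit. In ES the count of 5008 became 3117 with only the 2 groups, 222 with a log2 change of at least 1, 2531 at an adjusted p below 0.01 and 3026 in the weighted fit. For ES in control cells the count of 934 became 58 without a filter, 1675 with only the 2 groups, 75 with a log2 change of at least 1, 90 at an adjusted p below 0.01, 203 with a pseudocount of 0.1 and no filter, 231 with quantile normalisation, 2523 in the weighted fit and 1468 without the GC trend. For ES in FDX1-OE cells 7334 became 838 with a log2 change of at least 1. The interaction's 2291 became 3870 with equal totals, 1339 without a filter, 256 with a log2 change of at least 1, 432 at an adjusted p below 0.01, 999 with a pseudocount of 0.1 and no filter, and 1400 with quantile normalisation. Leaving out each library in turn, with the lone sample assumed to vary like the other groups, the counts ranged over 1 to 3, 2499 to 5277, 28 to 2342, 5530 to 7423 and 535 to 3462 in the same order.

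The results that reversed in this sense had values between -0.13 and 0.05 in the planned fit. FDX1 with ES in FDX1-OE cells was -0.23 with median-ratio scaling, -0.20 without the length trend and -0.23 without the GC trend, and 0.19 with equal totals. With equal totals the medians turned positive between FDX1-OE and control in ES for endoplasmic reticulum stress (UPR) (0.0937), fatty acid synthesis and desaturation (0.129), mitosis (G2/M) (0.0148), B cell and germinal centre identity (0.0893) and proteasome (0.0163). With ES in FDX1-OE cells they did for B cell and germinal centre identity (0.059), MHC class II (0.0629) and immediate early genes (0.0883), and in the interaction for fatty acid synthesis and desaturation (0.0381), mitosis (G2/M) (0.0333), B cell and germinal centre identity (0.0811) and proteasome (0.0062). With ES in control cells MHC class II was -0.11 with median-ratio scaling and -0.10 without the length trend, and cytosolic ribosomal proteins 0.0126 with quantile normalisation. With ES in FDX1-OE cells endoplasmic reticulum stress (UPR) was -0.27 with median-ratio scaling, -0.10 with quantile normalisation and -0.29 without the length trend, and mitosis (G2/M) was -0.24 with median-ratio scaling. In the interaction endoplasmic reticulum stress (UPR) was -0.16 with median-ratio scaling and -0.15 without the length trend. Depth limits the genes below 1 FPKM, where 1 fragment in the shortest gene models is taken as 0.138 to 0.164 FPKM.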

Other observations

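The tests on mitochondrial tRNA genes in this part were all chosen after the result was seen. Counts of further lists with ES in FDX1-OE cells stand against 5682 of 12063 genes higher and 1652 lower. The BCL2 family had 9 of 14 higher and 0 lower (the same adjusted over the list alone, set test adjusted p = 0.285), with BMF (1.57), PMAIP1 (0.82) and BCL2L11 (0.82), which promote apoptosis, and BCL2L1 (0.68), which opposes it. Autophagy and lysosome genes had 12 of 15 higher and 0 lower (the same adjusted over the list alone, set test adjusted p = 0.0161, adjusted p = 0.25 with an estimated correlation), among them SQSTM1 (1.22) and CTSB (1.56). Iron handling had 9 of 14 higher and 1 lower (the same adjusted over the list alone, set test adjusted p = 0.766), with FTH1 (1.53) and FTL (1.00) higher and the iron chaperone PCBP1 lower (-0.80). Haem biosynthesis had 8 of 13 higher and 2 lower (the same adjusted over the list alone, set test adjusted p = 0.394), with its first enzyme ALAS1 at 0.81. Ferroptosis regulators had 7 of 12 higher and 2 lower (the same adjusted over the list alone, set test adjusted p = 0.603), with SAT1 (0.95), SLC7A11 (1.54) and CHAC1 (2.88). Plasma cell differentiation had 5 of 8 higher and 2 lower (the same adjusted over the list alone, set test adjusted p = 0.705), with IRF4 (1.57) and SLAMF7 (1.47) higher and MZB1 (-0.46) lower. The proteasome had 0 of 31 higher and 14 lower (0 and 13 adjusted over the list alone, set test adjusted p = 7.97e-08, adjusted p = 0.217 with an estimated correlation), such as PSMC1 (-0.52). The signs of these medians held under the other scalings, but the counts did not. With median-ratio scaling the BCL2 family had 5 higher and 4 lower, autophagy 8 higher and 0 lower, iron handling 5 higher and 5 lower, haem biosynthesis 4 higher and 2 lower, ferroptosis 4 higher and 3 lower, plasma cell genes 3 higher and 2 lower and the proteasome 0 higher and 25 lower.

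In other groups the sign of the list's median turned under at least 1 scaling with ES in FDX1-OE cells, and in all of these but MHC class II called members went both ways. p53 targets had 7 of 18 higher and 2 lower (the same adjusted over the list alone, set test adjusted p = 0.904), with the cell cycle inhibitor CDKN1A at 2.36 and AEN at -0.51. S phase genes had 11 of 27 higher and 3 lower (11 and 2 adjusted over the list alone, set test adjusted p = 0.559), with the cyclin CCNE2 (1.96) and RRM2 (0.89) higher. Mitosis genes had 7 of 26 higher and 3 lower (5 and 3 adjusted over the list alone, set test adjusted p = 0.144), with CDC20 (-0.66), CCNB1 (-0.87) and PLK1 (-0.77) lower and MKI67 higher (0.44). Endoplasmic reticulum stress genes had 4 of 18 higher and 7 lower (the same adjusted over the list alone, set test adjusted p = 0.00446, adjusted p = 0.31 with an estimated correlation), with the chaperone HSPA5 at -1.24. Immediate early genes had 4 of 16 higher and 7 lower (the same adjusted over the list alone, set test adjusted p = 0.0195, adjusted p = 0.681 with an estimated correlation), with ATF3 (2.66) and DUSP5 (1.38) higher. B cell and germinal centre genes had 8 of 27 higher and 10 lower (the same adjusted over the list alone, set test adjusted p = 0.0039, adjusted p = 0.25 with an estimated correlation), with SERPINA9 (0.72) higher and BCL6 (-0.52) and MEF2B (-0.52) lower. MHC class II had 0 of 13 higher and 5 lower (0 and 3 adjusted over the list alone, set test adjusted p = 0.00549, adjusted p = 0.458 with an estimated correlation), with HLA-DPB1 at -0.53. The tricarboxylic acid cycle had 6 of 17 higher and 2 lower (6 and 1 adjusted over the list alone, set test adjusted p = 0.365), with SDHC at 0.57, and hypoxia genes had 3 of 14 higher and 2 lower (the same adjusted over the list alone, set test adjusted p = 0.384), with DDIT4 at 0.47. With median-ratio scaling p53 targets had 5 higher and 5 lower, S phase 7 higher and 7 lower, mitosis 3 higher and 14 lower, endoplasmic reticulum stress 1 higher and 11 lower, immediate early genes 3 higher and 8 lower, B cell genes 2 higher and 16 lower, MHC class II 0 higher and 11 lower, the tricarboxylic acid cycle 3 higher and 11 lower and hypoxia 0 higher and 6 lower. Among markers of other cells, VIM rose (1.54) and DCN fell (-0.67), the 2 epithelial and fibroblast markers tested, while 1 T and NK cell marker (TRAC) and 1 myeloid marker (AIF1) were tested.

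Mitochondrial tRNA genes moved apart with ES. Noise of short gene models is argued against, since their changes in control and FDX1-OE cells, which share no library, had a Pearson's r of 0.907 across 22 genes (Spearman's rho 0.892, permutation p = 1e-05, the smallest that 100000 resamples give, and r 0.875 without the 2 farthest genes), though genes are not independent replicates. Fragments that follow the level of the neighbouring genes are argued against for the rising tRNA genes, since 10 of the 11 exceeded both neighbours. Fragments of unprocessed transcripts that join a tRNA to its neighbours need not follow that level, so the test cannot decide on them. The falling tRNA genes were not tested in this way, and for them fragments of neighbouring mRNAs stay open. Some lay near a neighbour, such as MT-TS1 (-1.04) beside MT-CO1 (-0.99), while MT-TT lay below both MT-CYB (-0.70) and MT-RNR1 (-0.51). A common change in the amount of mitochondrial RNA is argued against as the whole cause, since 18 of the 22 lay further than 2 times their SE from the median of all 37 mitochondrial genes (-0.51), with MT-TK at 4.39 (SE 0.18) and MT-TT at -1.42 (SE 0.15). A candidate explanation is altered processing of the long mitochondrial transcripts, which was not tested, since the files hold no reads, and how well the library method captures such short RNAs stays open.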
